A study of Mus musculus with 12 samples.

How the data were processed

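RNA from wounds of the back skin of streptozotocin-diabetic C57BL/6 mice was sequenced, with 1 library per mouse and 12 mice. Per the labels, total RNA was extracted with a miRNeasy kit and made into libraries with an Illumina TruSeq RNA kit, and no strand setting is given. The deposited files hold raw read counts per gene symbol, 1 file per library, with 24062 genes and 5 summary lines of the counting tool. Per the submitters' processing notes, the authors used FastQC, TopHat2, Bowtie2, HTSeq and limma with the mouse build mm10. Versions, settings and the annotation behind the counts are not stated there. The deposited counts were found to be whole numbers with a different total in each library.

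Libraries were grouped by the treatment label alone, into pre-MCS-01, post-MCS-01, DSCG and blank, 3 libraries each. The labels give no batch, dose, time or pairing, and all mouse numbers differ. Replicates are numbered in the order of the records. All 6 pairs of groups were compared, 3 of them against blank and 3 of them between treatments, together with a joint test of the 4 groups. The 12 libraries hold 3.84e+06 to 5.05e+07 gene counts. A count of 0 over a group is read against a floor of 3 counts over that group, and ratios with 1 to 3 counts are given with an exact 95% binomial (Clopper-Pearson) counting interval.

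Counts were analysed in R 4.3.3. Genes with low counts were removed with filterByExpr at its defaults, which left 16267 genes, and libraries were scaled with TMM factors (0.905 to 1.07). Differences were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in 1 model of all 12 libraries with a mean per group. P values were adjusted by Benjamini-Hochberg over the genes tested, and the threshold was an adjusted p under 0.05 with no minimum fold. The biological coefficient of variation was 0.347. With 3 libraries against 3, the smallest two-sided exact permutation p for a single value is 0.1, so single genes were tested by the model that pools the spread across genes. An adjusted p in the text comes from this edgeR model, or from camera for a list, unless another tool is named. Errors of fold changes are standard errors, and errors of CPM are standard deviations over 3 libraries. Log2 CPM values used a prior count of 2.

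Lists of marker genes were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, two-sided, adjusted over the lists), with the correlation estimated per list as an alternative. Of 32 lists, 31 had at least 5 tested members. The mitochondrially encoded genes are not among the symbols counted, and that list was not analysed here. The 31 lists are mast cell, general macrophage, classically activated macrophage (M1), alternatively activated macrophage (M2), neutrophil, inflammatory cytokines and chemokines, interferon response, MHC class II, T and NK cell, B and plasma cell, collagen and matrix, myofibroblast and smooth muscle, matrix proteases, wound growth factors, endothelium, wound-activated keratinocyte, basal keratinocyte, epidermal differentiation, hair follicle, sebaceous gland, adipocyte, skeletal muscle, nerve and Schwann cell, neuropeptides, melanocyte, blood, cell cycle, hypoxia and glycolysis, immediate early and heat shock, oxidative stress, and ribosomal protein. Some genes stand in more than 1 list.

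The comparisons, the tests, the lists, the rule for naming genes and the first set of other processing choices were fixed before the data were examined. The rule names, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold with a mean of at least 1 CPM and no overlap between the groups. Predicted genes are not named. Where fewer than 10 genes pass, it names the 10 with the smallest p. It adds up to 4 members of each list that passes, up to 2 of each other list, and, against blank, 14 fixed genes. For post-MCS-01 against DSCG, 1 gene that the rule names is not reported here.

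Fixed beforehand as other ways to process the counts were RLE scaling, total-count scaling, no filter on low counts, DESeq2 1.42.0, limma-voom, limma-voom with library quality weights, a fit of the 2 groups compared, camera with an estimated correlation, and leaving out each library in turn. Chosen after the data were seen were edgeR's newer quasi-likelihood fit, a fit without 3 libraries short of long transcripts, a fit with each library's exon-length trend as a covariate, an exact permutation of list means over 15400 splits, and differences of list means in log2 CPM without each library in turn. Exon lengths and coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 names, matched by symbol. A length was found for 95.3% of genes. A shared response of the treatments was set beside 100 simulated draws of counts without any effect, and other splits of the same libraries were counted, 10 per pair of groups and 100 for the joint test.

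The steps were tested on simulated data with known changes in the post-MCS-01 group. For post-MCS-01 against blank, the test recovered 14.9% of genes changed 2-fold, 71.6% of those changed 4-fold and 97.0% of those changed 16-fold, and it called 5 genes that had not been changed. For post-MCS-01 against DSCG it recovered 7.46%, 73.1% and 95.5%, with 5 false calls, and for pre-MCS-01 against post-MCS-01 it made 3 false calls. In the comparisons without a simulated change it called 0 genes. The simulated genes varied independently, without any trend shared by libraries, and only genes with a mean of at least 1 CPM were changed. These rates therefore need not hold for the real libraries, which share such trends.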

Results

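Back-skin wounds of C57BL/6 mice made diabetic with streptozotocin were profiled by RNA sequencing after treatment with MCS-01, a mast cell stabilizer known here only by its code name. Per the labels, 12 mice gave 1 library each, in 4 treatment groups of 3: pre-MCS-01, post-MCS-01, DSCG and blank. DSCG is the usual abbreviation of disodium cromoglycate, an established mast cell stabilizer, and blank was taken as the control. The labels do not define pre and post and give no dose or time, so each label was treated as a group of its own. The deposited values were raw read counts per gene, and levels are given as CPM, the counts scaled to a common library total after TMM scaling.

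Gene counts totalled 4.07e+07, 3.89e+07 and 4.44e+07 in the pre-MCS-01 libraries, 3.77e+07, 4.29e+07 and 4.09e+07 in post-MCS-01, and 4.02e+07, 4.83e+07 and 4.42e+07 in DSCG. Among the blank libraries they totalled 5.05e+07, 4.57e+07 and 3.84e+06, so blank replicate 3 was far shallower than the other 11. A count of 0 in a library allowed up to 0.786 CPM in blank replicate 3 (3 counts) and up to 0.0588 to 0.0852 CPM in the other 11. Floors and counting intervals cover counting error only. The first principal component of log2 CPM held 44.4% of the variance and set the 3 post-MCS-01 libraries (68.9 to 100.1) apart from the other 9 (-72.6 to 33.9).

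Transcript length separated 3 libraries from the rest. In pre-MCS-01 replicate 2, DSCG replicate 2 and blank replicate 3, genes with long exons lay lower relative to the average library, with Spearman's rho across genes of -0.385, -0.330 and -0.320 against log exon length. The other 9 libraries lay between -0.0561 and 0.336. Genes are not independent replicates, so these values describe a trend and are not a test. The same 3 libraries lay highest on the second component (17.8% of the variance), between 33.8 and 62.5, with the other 9 between -51.9 and 25.8. On the first component they lay between -72.6 and -38.0, and the other 9 between -57.6 and 100.1. None of the 3 was a post-MCS-01 library, so the first component need not reflect that group alone.

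**Figure D1:**
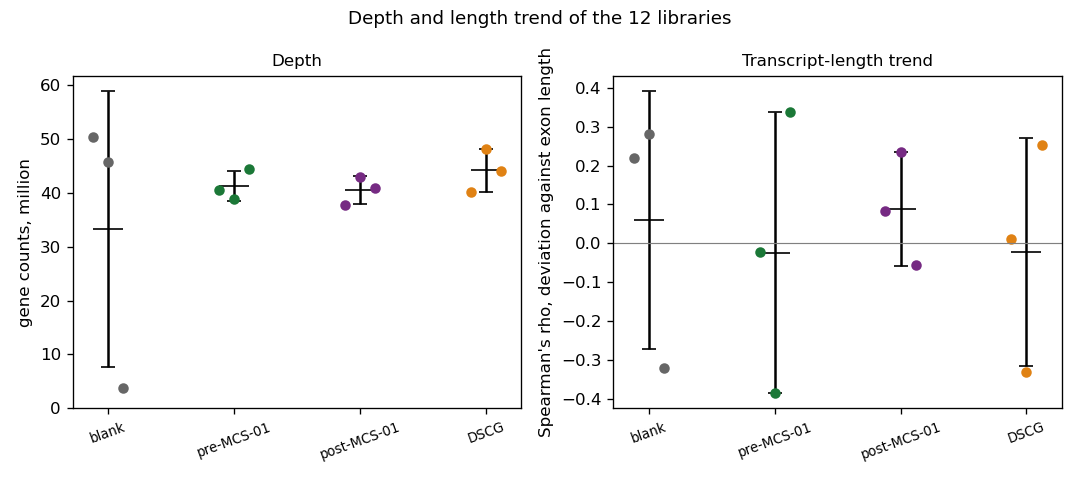
Left, total gene counts per library, and right, Spearman's rho across genes between a library's deviation from the average library and log exon length, for the 4 groups (points, libraries; bars, mean ± SD, n = 3). Blank replicate 3 holds 3.84e+06 counts, and 3 libraries of 3 groups lie at -0.320 or lower in the length trend.

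The comparison of pre-MCS-01 with post-MCS-01 asked whether wounds under these labels differ from each other. Genes of the hair shaft and its root sheath were far higher in pre-MCS-01 wounds. Trichohyalin (Tchh, chromosome 3, 93442330 to 93449077), a structural protein of the inner root sheath, stood at 5612 ± 1515 CPM in pre-MCS-01 and 31.5 ± 9.53 CPM in post-MCS-01 (SD, n = 3 each), a 178-fold difference (log2 fold change 7.48 ± 1.10 SE, adjusted p = 0.0313). Padi3 (chromosome 4, 140785365 to 140810648), an enzyme that modifies trichohyalin, was 247-fold higher at 330 ± 183 against 1.33 ± 0.922 CPM (adjusted p = 0.0313). The hair keratins Krt33a and Krt31 were higher by log2 fold changes of 10.68 ± 1.52 and 10.25 ± 1.47 (SE). These were 9.72 and 9.39 without pre-MCS-01 replicate 2 (adjusted p = 0.0682 each) and 11.84 and 11.44 without post-MCS-01 replicate 1 (adjusted p = 0.141 each).

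Among the 10 genes with the largest rise, 4 had no count in any post-MCS-01 library. The keratin-associated protein genes Krtap5-4, Krtap24-1 and Krtap5-3 were at least 800-fold, 698-fold and 390-fold higher in pre-MCS-01, and Bhlha9 at least 768-fold, against a floor of 3 counts over the group. A further 4 had 1 to 3 counts over the post-MCS-01 group. For these the ratio was 5327 for Krtap19-4 (95% counting interval 1474 to 43995), 4801 for Lyg2 (1329 to 39652), 4640 for Krtap5-2 (832 to 183310) and 3506 for Krtap1-4 (1199 to 17005). Krtap14 and Krtap15 complete the 10, with 6 and 14 counts in post-MCS-01 and 17971 and 28433 in pre-MCS-01. The folds of all 10 were over 1.5 times smaller without pre-MCS-01 replicate 2, with Krtap15 and Krtap14 at log2 fold changes of 9.50 and 9.96. Reads matching more than 1 place were left out of the deposited counts, so levels within the Krtap family depend on the positions at which its copies differ.

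In the other direction, 3 genes were lower in pre-MCS-01 than in post-MCS-01. C7 (chromosome 15, 4988762 to 5063740), a terminal complement component, fell by 2.91 ± 0.48 on the log2 scale (6.09 ± 1.87 against 46.0 ± 24.0 CPM, adjusted p = 0.0313). Lyve1 (chromosome 7, 110850607 to 110863239), a hyaluronan receptor of lymphatic endothelium and of some tissue macrophages, fell by 1.59 ± 0.23 (10.1 ± 1.95 against 30.4 ± 8.84 CPM, adjusted p = 0.0313). Il13ra2 (chromosome X, 147383476 to 147429192), a receptor that binds interleukin 13, fell by 1.51 ± 0.28 (adjusted p = 0.0383).

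In all, 134 of 16267 genes passed (edgeR quasi-likelihood, adjusted p under 0.05), 131 higher and 3 lower in pre-MCS-01, and 65 of the 131 carried a keratin or keratin-associated symbol, out of 102 such genes tested. The 3 values of each group did not overlap in any of the 134. These genes were chosen by small p in the same libraries, so this is no separate support. Over all genes, 17.7% did not overlap, against 10% expected by chance. The count was 0 without pre-MCS-01 replicate 2 or without any 1 of the post-MCS-01 libraries, 48 without pre-MCS-01 replicate 3, and 0 without the 3 libraries short of long transcripts. It was 425 with DESeq2, 3818 with limma-voom and library quality weights, 1 with limma-voom and 1 with exon length as a covariate.

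Gene lists fixed from textbook markers described the same difference by cell type. All 27 tested members of the hair follicle list were higher in pre-MCS-01, 23 of them past the threshold over all genes and 27 adjusted over the list alone, with a median log2 fold change of 8.58 and no member at 0 in a group. The list passed camera (adjusted p = 6.07e-72 with the preset correlation), and adjusted p = 0.0448 with an estimated correlation. The melanocyte list rose as well (mean log2 fold change 4.04, adjusted p = 3.18e-19), with adjusted p = 0.129 with an estimated correlation. None of its 10 members passed over all genes and 10 adjusted over the list alone, among them Pmel, a melanosome matrix protein (3.73 ± 0.78), and Oca2 (5.99 ± 1.23).

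Markers of alternatively activated macrophages (M2) were lower in pre-MCS-01 than in post-MCS-01, with a mean log2 fold change of -1.06 (adjusted p = 2.06e-11, and adjusted p = 0.0448 with an estimated correlation). Of its 17 members, 1 fell over all genes (Lyve1) and 10 adjusted over the list alone. The scavenger receptor genes Mrc1 and Cd163 stood 2.82-fold and 3.53-fold lower (SE 0.36 and 0.46 on the log2 scale), and the chitinase-like Chil3 4.24-fold lower (SE 0.56). Beside these, the general macrophage list fell (mean -0.73, adjusted p = 3.05e-07, 0 members over all genes and 2 adjusted over the list alone, Cd68 and Fcgr3), with adjusted p = 0.387 with an estimated correlation. The M1 list (mean -0.78, adjusted p = 0.00112) and the inflammatory list (mean -0.85, adjusted p = 0.000646) fell too, with no member past either threshold and adjusted p = 0.490 for each with an estimated correlation, so the fall was not particular to M2 markers. In mean log2 CPM the M1 difference of -0.58 was -0.26 without pre-MCS-01 replicate 2 and -0.34 without post-MCS-01 replicate 2, and without the latter the inflammatory difference went from -0.69 to -0.32 (adjusted p = 0.103). The MHC class II list (mean -0.84, adjusted p = 5.44e-07), the skeletal muscle list (-0.79, 2.28e-06) and the wound growth factor list (-0.38, 0.00423) fell with the preset correlation, and adjusted p = 0.424, 0.490 and 0.490 with an estimated correlation, with no member past either threshold. In mean log2 CPM the skeletal muscle difference of -0.76 was -0.48 without post-MCS-01 replicate 3, and the wound growth factor difference of -0.39 was -0.25 and -0.63 without pre-MCS-01 replicates 2 and 3. In this comparison 22 of 31 lists passed with the preset correlation and 2 with an estimated one, hair follicle and M2.

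**Figure D2:**
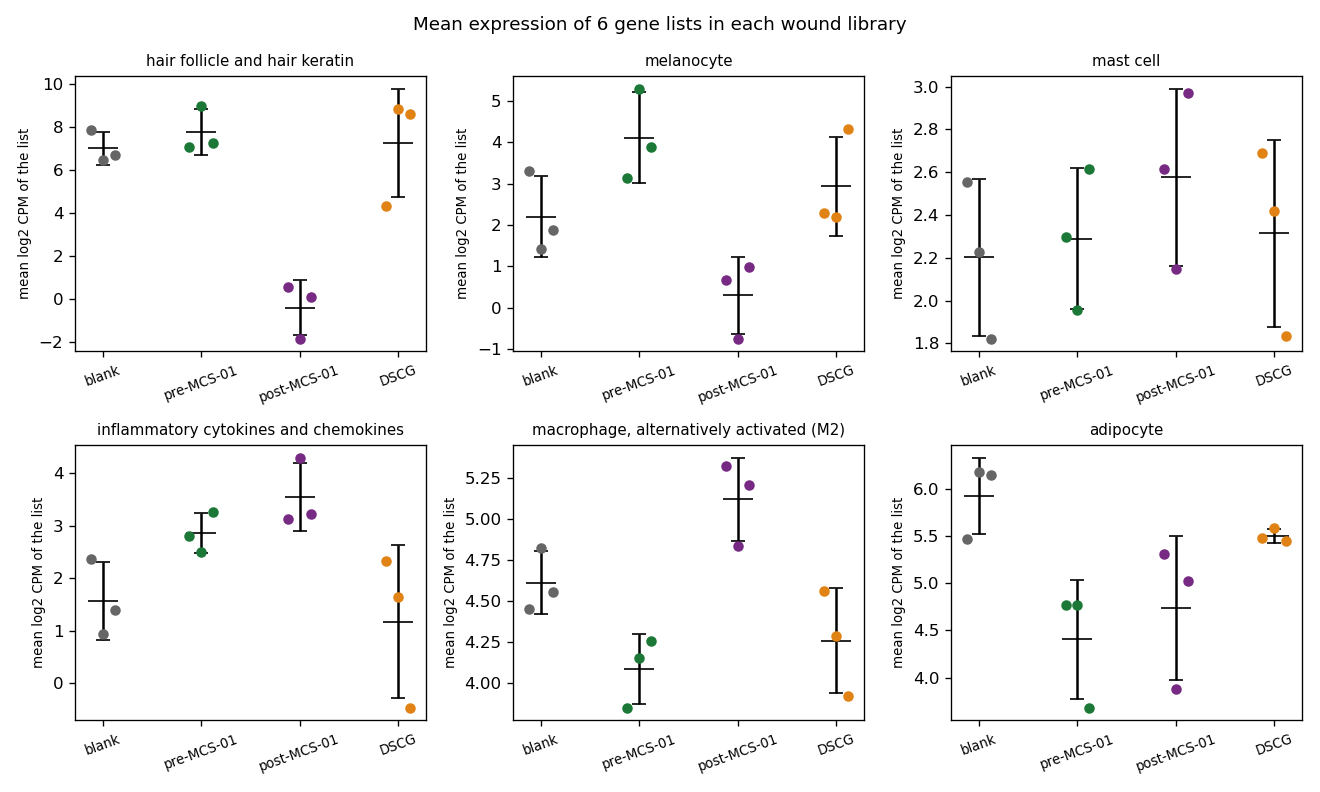
Mean log2 CPM of 6 gene lists in each library, by group (points, libraries; bars, mean ± SD, n = 3). The hair list averages -0.38 ± 1.28 in post-MCS-01 and 7.02 ± 0.76 in blank, and the mast cell list overlaps between all 4 groups.

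The comparison of post-MCS-01 with DSCG set the coded compound beside an established stabilizer, with dose and time not stated for either. Of the genes tested, 23 were higher in post-MCS-01 wounds, and no common theme among the 23 was tested. Gzmb (chromosome 14, 56258838 to 56262260), a protease of cytotoxic lymphocytes, was 5.80-fold higher at 7.15 ± 1.79 against 1.23 ± 0.362 CPM (log2 fold change 2.54 ± 0.32 SE, n = 3 each, adjusted p = 0.0288). Chil3 was 9.94-fold higher at 35.5 ± 18.7 against 3.57 ± 2.52 CPM (adjusted p = 0.0323). The anion exchanger gene Slc26a4 (chromosome 12, 31519827 to 31559969) was 92.1-fold higher, at 67.0 ± 72.0 against 0.736 ± 0.780 CPM (log2 fold change 6.53 ± 1.14, adjusted p = 0.0323). Post-MCS-01 replicate 2 held 148 CPM of Slc26a4, and without it the log2 fold change was 5.19 (adjusted p = 0.166). Without DSCG replicate 1 it was 7.83 for Slc26a4 (adjusted p = 0.00848) and 4.00 for Chil3 (0.00504).

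Others among the 10 largest rises were Il12b, which encodes the shared subunit of interleukins 12 and 23 (5.38 ± 1.00, SE), the interleukin 10 family cytokine Il20 (5.23 ± 0.85), U90926 (5.26), Spdef (4.89), Tnfrsf8 (3.64), Rnd1 (2.96) and the tight junction gene Cldn17 (2.92), each as log2 fold change with adjusted p between 0.0323 and 0.0470. Without post-MCS-01 replicate 2 the log2 fold changes of Il12b, Il20 and Rnd1 were 4.42, 4.59 and 2.22 (adjusted p = 0.168, 0.165 and 0.194), and without DSCG replicate 1 those of U90926, Spdef and Rnd1 were 7.21, 6.50 and 3.79. Without DSCG replicate 3 that of U90926 was 4.63 (adjusted p = 0.0938), and without DSCG replicate 2 that of Il20 was 5.83 (adjusted p = 0.0995). Ccr7, a homing receptor of dendritic and T cells, rose 3.86-fold (adjusted p = 0.0353). Il13ra2 rose by 1.45 ± 0.28 (adjusted p = 0.0382) and was the 1 gene higher in post-MCS-01 in both this comparison and the one with pre-MCS-01, which use the same 3 post-MCS-01 libraries.

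Hair genes were lower in post-MCS-01 than in DSCG, as they were against pre-MCS-01. Tchh stood at 31.5 ± 9.53 against 7592 ± 8257 CPM (log2 fold change -7.92 ± 1.12, adjusted p = 0.0288) and Padi3 at 1.33 ± 0.922 against 501 ± 405 CPM (-8.55 ± 1.20, adjusted p = 0.0288). Krtap5-4 and Bhlha9 had no count in post-MCS-01 and were at least 831-fold and 359-fold lower. Krtap1-4 and Krtap26-1, with 3 and 2 counts, were lower by ratios of 4736 (95% counting interval 1620 to 22970) and 3637 (1006 to 30036). Krtap11-1, Krt72, Krtap1-3, Krt81, Krtap14 and Krtap15, with 5 to 37 counts in post-MCS-01, were lower by log2 fold changes of -11.91 to -11.19. Without DSCG replicate 2 the log2 fold changes of Krtap14, Krtap1-4, Krtap15 and Krtap11-1 were -10.99, -10.92, -10.51 and -10.47. Those of Krtap1-3, Krt81, Krtap26-1 and Bhlha9 were -10.40, -10.39, -10.36 and -10.32. None of these passed there, with adjusted p between 0.0804 and 0.141. Without post-MCS-01 replicate 2 Krt72 was at -10.62 (adjusted p = 0.165). Post-MCS-01 replicate 1 held all 6 counts of Krtap14 in its group, so without it the gene is at 0 there. The erythrocyte anion exchanger Slc4a1 also fell, by 5.34 ± 0.95 (adjusted p = 0.0334), and was the 1 member of the blood list past the threshold over all genes. Without DSCG replicate 3, the log2 fold changes of Tchh and Slc4a1 were -6.56 and -4.32 (adjusted p = 0.0760 and 0.0933).

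Here 172 genes passed (edgeR), 23 higher and 149 lower in post-MCS-01, 61 of the 149 with a keratin or keratin-associated symbol. None of the 172 overlapped between groups, which is again no separate support for genes chosen by small p. Over all genes, 15.4% did not overlap, against 10% by chance. Of the 149, 119 were also lower in post-MCS-01 than in pre-MCS-01, in comparisons that share the 3 post-MCS-01 libraries and so are not independent. The count was 606 without DSCG replicate 1, the DSCG library with the lowest hair gene levels, and 0 without any other 1 of the 6 libraries. It was 613 with DESeq2, 2 with limma-voom and 0 with library quality weights, with a fit of these 6 libraries alone, with exon length as a covariate, and without the 3 libraries short of long transcripts.

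By list, all 27 hair genes were lower in post-MCS-01 than in DSCG (median log2 fold change -8.94, 24 past the threshold over all genes, 27 adjusted over the list alone, adjusted p = 3.2e-61), with adjusted p = 0.0856 with an estimated correlation. The melanocyte list fell (mean -2.96, adjusted p = 7.64e-11, 0 members over all genes and 9 of 10 adjusted over the list alone), with adjusted p = 0.231 with an estimated correlation. The inflammatory cytokine and chemokine list rose (mean 2.12, adjusted p = 9.24e-15, 24 of 25 members positive, 0 over all genes and 9 adjusted over the list alone), with adjusted p = 0.0856 with an estimated correlation. Its members include the neutrophil chemoattractant Cxcl1 (3.35 ± 0.89, adjusted p = 0.131) and the epithelial alarmin Il33 (1.86 ± 0.49, adjusted p = 0.129). Without DSCG replicate 3, the difference of the list in mean log2 CPM went from 2.38 to 1.57.

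The macrophage and neutrophil lists passed between post-MCS-01 and DSCG with the preset correlation and not with an estimated one. The general macrophage list rose by 0.52 (adjusted p = 0.00745, 0 members past either threshold), with adjusted p = 0.550 with an estimated correlation, 0.252 without DSCG replicate 3 and 0.201 without post-MCS-01 replicate 3, and its difference in mean log2 CPM went from 0.55 to 0.26 without DSCG replicate 3. The classically activated macrophage (M1) list rose by a mean of 1.84 (adjusted p = 2.98e-09, 16 of 16 members positive, 2 over all genes, Il12b and Ccr7, and 3 adjusted over the list alone) and the M2 list by 0.85 (adjusted p = 9.94e-07, 1 over all genes, Chil3, and 5 adjusted over the list alone). With an estimated correlation these had adjusted p = 0.116 and 0.0856. The neutrophil list rose by 1.71 (adjusted p = 2.98e-09, 0 over all genes and 2 adjusted over the list alone), and adjusted p = 0.331 with an estimated correlation, with Lcn2, a neutrophil granule protein, at 2.52 ± 0.58. The protease list rose by 0.84 (adjusted p = 3.49e-06, 0 over all genes and 1 adjusted over the list alone), and adjusted p = 0.271 with an estimated correlation. The T and NK cell list rose by 0.45 (adjusted p = 0.00154, 1 over all genes, Gzmb, and 2 adjusted over the list alone), with adjusted p = 0.550 with an estimated correlation and adjusted p = 0.106 without DSCG replicate 3. The hypoxia and glycolysis list rose by 0.67 (adjusted p = 1.88e-06, and adjusted p = 0.331 with an estimated correlation), with no member past either threshold. DSCG replicate 3 lay low in neutrophil genes, and without it the difference in mean log2 CPM went from 2.02 to 1.08. The T and NK cell difference of 0.64 was 1.16, 0.40 and 0.37 without DSCG replicates 1, 2 and 3, and the hypoxia difference of 0.63 was 0.38 without post-MCS-01 replicate 2. In this comparison 16 lists passed with the preset correlation and 0 with an estimated one. Lists of other cell types were among the 16. In mean log2 CPM the wound-activated keratinocyte difference of 1.75 was 0.63 without DSCG replicate 3. The adipocyte difference of -0.76 was -0.33 without post-MCS-01 replicate 2. The skeletal muscle difference of 0.49 ranged from 0.21 without post-MCS-01 replicate 3 to 0.80 without DSCG replicate 1.

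**Figure D3:**
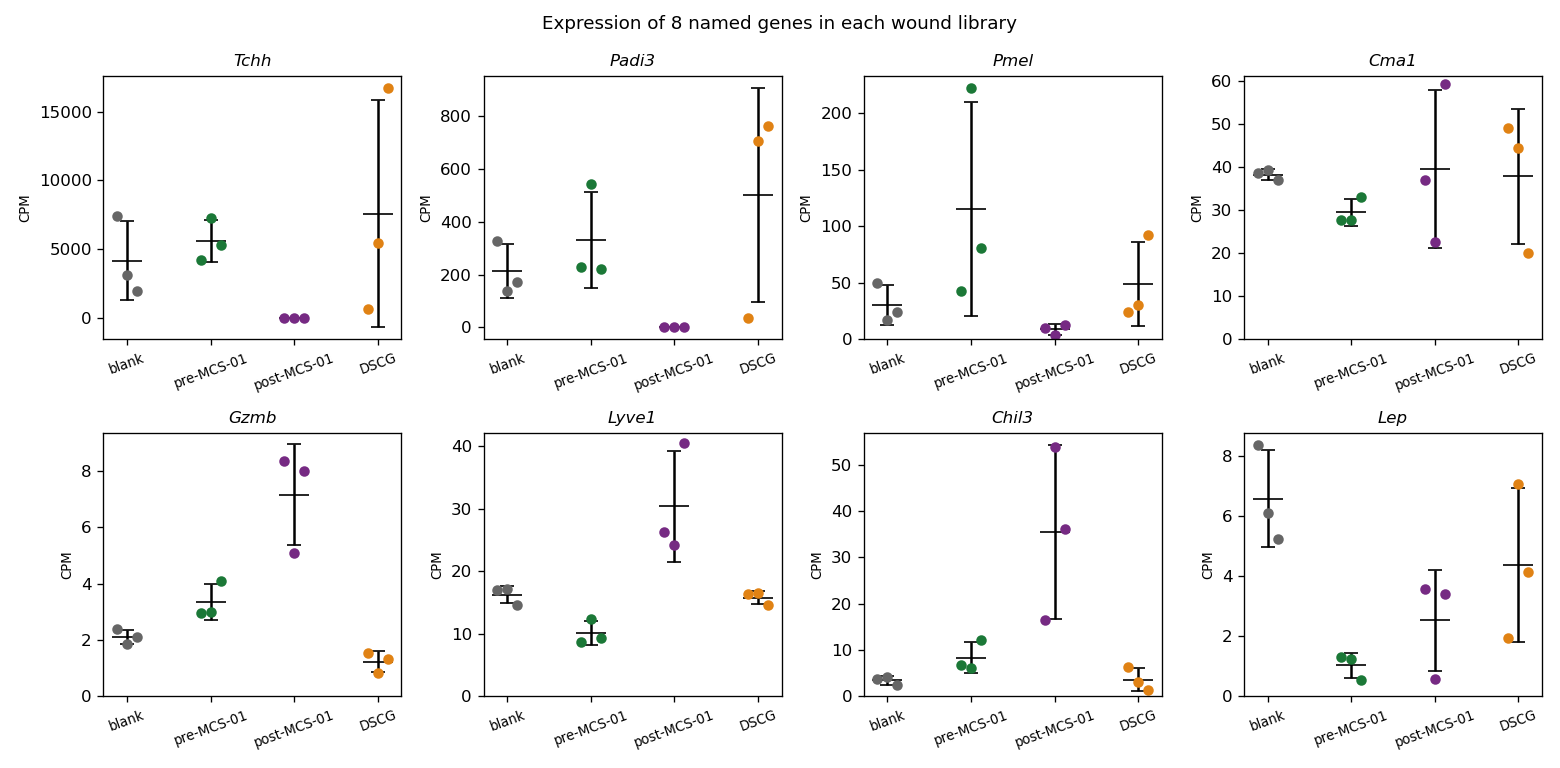
CPM of 8 genes in each library, by group, on linear axes (points, libraries; bars, mean ± SD, n = 3). Tchh and Padi3 are near 0 in post-MCS-01 and spread widely in DSCG, Gzmb, Lyve1 and Chil3 are highest in post-MCS-01, and Cma1 overlaps between blank, post-MCS-01 and DSCG.

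Against blank, post-MCS-01 asked how treated wounds differed from control wounds. No gene passed (edgeR, smallest adjusted p = 0.0692), and the 10 genes with the smallest p were all lower in post-MCS-01. They were Tchh (31.5 ± 9.53 against 4175 ± 2869 CPM, log2 fold change -7.05 ± 1.08), Padi3 (-7.31 ± 1.14), Krt33a, Krt31, Krt72, Krt26, Krtap11-1, Crnn, Fam26d and Lyg2. Fam26d and Lyg2 had 2 counts each over the post-MCS-01 group, lower by ratios of 1100 (95% counting interval 304 to 9093) and 933 (258 to 7715). Among genes with higher values were Chil3 (3.30 ± 0.60, adjusted p = 0.0729), Gzmb (1.76 ± 0.32, adjusted p = 0.0729), the mitochondrial superoxide dismutase Sod2 (1.05 ± 0.19, adjusted p = 0.0729), the beta-defensin Defb3 (6.03 ± 1.19, adjusted p = 0.0787) and the cystine transporter Slc7a11 (3.17 ± 0.69, adjusted p = 0.0875).

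By list, the 27 hair genes fell against blank (median -7.45, 0 past the threshold over all genes and 27 adjusted over the list alone, adjusted p = 1.77e-74), with adjusted p = 0.0610 with an estimated correlation. The inflammatory list rose by a mean of 1.94 (adjusted p = 3.32e-11, 2 members adjusted over the list alone, Il33 and Il19), the M1 list by 1.57 (7.28e-08, 2), the M2 list by 0.56 (0.000532, 4) and the neutrophil list by 1.80 (1.52e-08, 1). With an estimated correlation these had adjusted p = 0.201, 0.201, 0.201 and 0.324. The oxidative stress list rose by 0.49 (adjusted p = 0.000532, 4 adjusted over the list alone), with adjusted p = 0.0610 with an estimated correlation. The wound-activated keratinocyte list rose by 1.88 (adjusted p = 3.54e-10, 8 members higher and 1 lower adjusted over the list alone), with adjusted p = 0.234 with an estimated correlation. The 1 lower was Krt75 (-2.68 ± 0.87), a keratin of the hair follicle's companion layer, chosen for naming after its value was seen. The melanocyte list fell by a mean of 2.14 on the log2 scale (adjusted p = 1.08e-07, 8 adjusted over the list alone) and the adipocyte list by 1.09 (8.42e-11, 3), with adjusted p = 0.303 and 0.201 with an estimated correlation. No member of these lists passed over all genes. Without post-MCS-01 replicate 2, the differences in mean log2 CPM went from 1.69 to 1.08 for the neutrophil list and from -1.19 to -0.76 for the adipocyte list.

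Between post-MCS-01 and blank, 1521 genes had an unadjusted p under 0.05, and 18.4% of genes did not overlap against 10% by chance. Genes are not independent, so this share is not by itself evidence of an effect. DESeq2 gave 396 genes, limma-voom 0, library quality weights 827, a fit of these 6 libraries alone 255, no filter on low counts 37 and the newer edgeR fit 63.

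Between pre-MCS-01 and blank wounds, no gene passed the threshold (edgeR, smallest adjusted p = 0.583). The 10 smallest p belonged to the iron carrier Trf (78.8 ± 8.06 against 169 ± 24.1 CPM, log2 fold change -1.10 ± 0.19), C7 (-2.44 ± 0.47), Cldn17 (2.46 ± 0.48), Pik3ip1 (-0.96 ± 0.19), Gsn (-1.24 ± 0.25), Tnxb (-1.68 ± 0.34), Cyp2e1 (-2.66 ± 0.55), Mgp (-1.88 ± 0.39), Hcar1 (-2.15 ± 0.45) and elastin, Eln (-1.77 ± 0.37). All 18 adipocyte genes were lower (mean -1.43, adjusted p = 8.66e-23, 0 over all genes and 12 adjusted over the list alone), with adjusted p = 0.213 with an estimated correlation. They include leptin, Lep (1.03 ± 0.416 against 6.57 ± 1.62 CPM), and the lipid droplet protein Plin4 (-1.76 ± 0.38).

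All 22 cell cycle genes were higher in pre-MCS-01 than in blank (mean 0.71, adjusted p = 5.64e-17, 0 over all genes and 11 adjusted over the list alone, with Cdc20 at 0.90 ± 0.22), with adjusted p = 0.246 with an estimated correlation. The wound-activated keratinocyte list rose by 1.78 (adjusted p = 1.78e-11, 2 adjusted over the list alone, Defb3 and Sprr2h), with adjusted p = 0.246 with an estimated correlation. The neutrophil list rose by 1.32 (adjusted p = 3.68e-05, 17 of 17 members positive, 0 past either threshold), with adjusted p = 0.427 with an estimated correlation. Its S100a8 and S100a9 stood at 1716 ± 591 and 3123 ± 670 CPM against 243 ± 78.3 and 448 ± 126. The inflammatory list rose by 1.09 (adjusted p = 0.000468), and the melanocyte list by 1.90 (1.43e-08), with adjusted p = 0.415 and 0.313 with an estimated correlation. The hair follicle list passed upward with the preset correlation (adjusted p = 0.00449) and not with an estimated one. In mean log2 CPM its difference of 0.75 was 0.14 without pre-MCS-01 replicate 2 (camera adjusted p = 0.833). It was 1.18 and 0.48 without blank replicates 1 and 2. Without the 3 libraries short of long transcripts the hair test turned in direction. The endothelial list fell by a mean of 0.57 on the log2 scale (adjusted p = 3.8e-06), the sebaceous gland list by 0.82 (2.84e-05), the nerve and Schwann cell list by 0.31 (0.00522) and the M2 list by 0.51 (0.000164). With an estimated correlation these had adjusted p = 0.415, 0.415, 0.313 and 0.246, and none had a member past either threshold. The general macrophage list (median -0.57, camera adjusted p = 0.000401) and the MHC class II list (median -0.49, 0.000107) fell too. Neither passed with an estimated correlation, and the fall was not particular to M2 markers. In mean log2 CPM the general macrophage difference of -0.31 was -0.13 without pre-MCS-01 replicate 2 and -0.19 without blank replicate 1. In mean log2 CPM the endothelial difference of -0.62 was -0.19 without pre-MCS-01 replicate 2, a library short of long transcripts, and -1.01, -0.39 and -0.95 without pre-MCS-01 replicate 3, blank replicate 1 and blank replicate 3. The sebaceous gland difference of -0.76 was -0.48 without blank replicate 2, and the nerve and Schwann cell difference of -0.34 was -0.22 and -0.52 without blank replicates 2 and 3.

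Between pre-MCS-01 and blank, 1178 genes had an unadjusted p under 0.05, and 14.4% of genes did not overlap against 10% by chance. The same share was 3.68% for DSCG against blank and 5.12% for pre-MCS-01 against DSCG. Genes are not independent, so a share above 10% is not by itself evidence of an effect. DESeq2 gave 74 genes, limma-voom 0, library quality weights 2485 and a fit of these 6 libraries alone 2.

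The comparison of DSCG with blank asked what the established stabilizer did to the control wound, and no difference in a single gene was detectable. No gene passed with edgeR, DESeq2, limma-voom or library quality weights, the smallest edgeR adjusted p was 0.999, and 167 genes had an unadjusted p under 0.05. The gene with the smallest p, AA467197, had a log2 fold change of -2.42 ± 0.53 (SE, n = 3 each). It was followed by Tnfsf18 (-1.84 ± 0.43), the alcohol dehydrogenase Adh7 (-0.91 ± 0.24), Ankrd9 (0.67 ± 0.19), B4galnt4 (0.81 ± 0.24), Arsk (-1.19 ± 0.35), Psca (-1.73 ± 0.53), Kcng1 (-2.67 ± 0.87), the mitochondrial serine enzyme Shmt2 (0.57 ± 0.19) and Ang2 (-1.75 ± 0.57). The cell cycle list rose by a mean of 0.38 (adjusted p = 3.36e-11, 21 of 22 members positive) and the sebaceous gland list fell by a mean of 0.62 on the log2 scale (adjusted p = 6.3e-07, 15 of 15 negative), with adjusted p = 0.831 for each with an estimated correlation. No member of any list passed over all genes or adjusted over the list alone. Of the 12 lists that passed with the preset correlation, these were the 2 that also passed without each library in turn, though their size moved. In mean log2 CPM the sebaceous gland difference of -0.67 was -0.34, -1.08 and -0.40 without DSCG replicate 2, DSCG replicate 3 and blank replicate 2, and the cell cycle difference of 0.42 was 0.68 and 0.23 without blank replicates 1 and 3. In this comparison 3.68% of genes did not overlap against 10% by chance.

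Between pre-MCS-01 and DSCG, no gene passed (edgeR, smallest adjusted p = 0.428, 384 genes at an unadjusted p under 0.05, 15 genes with DESeq2, 0 with limma-voom and 0 with library quality weights). The smallest p belonged to Cldn17 (3.17 ± 0.47), followed by Dusp15 (-2.20 ± 0.46), Il20 (3.97 ± 0.83), Trf (-0.89 ± 0.19), Gzmb (1.44 ± 0.31), Spdef (3.86 ± 0.84), Itih2 (-2.70 ± 0.59), Vtn (-1.57 ± 0.36), Aatk (-0.99 ± 0.22) and Rgl3 (-1.17 ± 0.27), as log2 fold change with SE, and 5.12% of genes did not overlap against 10% by chance. The adipocyte list fell by a mean of 0.99 on the log2 scale (adjusted p = 1.76e-21, 0 over all genes and 3 adjusted over the list alone), and the inflammatory list rose by 1.26 (4.48e-13), with adjusted p = 0.201 for each with an estimated correlation. The neutrophil list rose by 1.23 (1.01e-11) and the wound-activated keratinocyte list by 0.83 (3.38e-11), while the smooth muscle and myofibroblast list fell by a mean of 0.45 (7.65e-05), with adjusted p = 0.264, 0.255 and 0.338 with an estimated correlation and no member past either threshold. Without DSCG replicate 3, the differences in mean log2 CPM went from 1.69 to 0.88 for the inflammatory list, from 1.68 to 0.75 for the neutrophil list and from 1.72 to 0.60 for the wound-activated keratinocyte list. The hair list did not pass (adjusted p = 0.494) and its mean of -0.13 and its test differed in sign.

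Mast cell transcripts, the cell type both stabilizers address, did not differ past the threshold in any comparison against blank. These are transcript levels in whole wounds, and release of mast cell contents was not measured. The chymase gene Cma1 (chromosome 14, 55941451 to 55944675) stood at 38.3 ± 1.23 CPM in blank, 29.5 ± 3.18 in pre-MCS-01, 39.7 ± 18.4 in post-MCS-01 and 37.9 ± 15.6 in DSCG (SD, n = 3 each). Over Cpa3, Cma1, Mcpt4, Tpsb2 and Kit, the log2 fold changes against blank lay between -0.41 and 0.53 in pre-MCS-01, -0.73 and 0.05 in post-MCS-01, and -0.19 and 0.42 in DSCG. Their 95% intervals, not adjusted for multiple tests, reached from -1.16 to 1.42, -1.62 to 0.88 and -0.87 to 1.31 over the 5 genes together, and the interval of each gene is narrower. For Cpa3 in post-MCS-01 it was -0.73 to 0.64, and for Kit -1.62 to 0.16. Between the compounds the intervals reached from -1.24 to 0.99 for pre-MCS-01 against DSCG and from -2.05 to 0.85 for post-MCS-01 against DSCG. Kit, a receptor that melanocytes also carry, lay at -1.15 ± 0.41 in the latter (adjusted p = 0.279) and at 1.26 ± 0.41 between pre-MCS-01 and post-MCS-01 (adjusted p = 0.291). The 17-gene mast cell list did not pass against blank (adjusted p = 0.227 in pre-MCS-01, 0.391 in post-MCS-01 and 0.856 in DSCG). Between pre-MCS-01 and post-MCS-01 it passed at a mean of -0.35 (adjusted p = 0.0393, and adjusted p = 0.596 with an estimated correlation) but not without pre-MCS-01 replicate 1 (0.0857) or 2 (0.147), or post-MCS-01 replicate 1 (0.0756) or 3 (0.485). Its difference in mean log2 CPM, -0.29, was -0.12, -0.45, -0.50 and -0.09 without pre-MCS-01 replicates 2 and 3 and post-MCS-01 replicates 2 and 3.

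The remaining fixed genes gave values of the same kind, none past the threshold against blank. For pre-MCS-01, post-MCS-01 and DSCG in turn, the log2 fold changes were 2.47, 2.83 and -1.39 for the nitric oxide synthase Nos2 (SE 1.49, 1.51 and 1.48), 1.67, 1.71 and 0.25 for Arg1 (0.50, 0.50 and 0.49), and -0.93, 0.56 and -0.35 for Mrc1 (0.35 each). They were 2.10, 2.52 and -0.40 for Il1b (1.45 to 1.53), 1.24, 1.57 and -0.01 for Tnf (0.64, 0.64 and 0.63), and 2.55, 3.28 and 0.07 for Cxcl2 (1.86, 1.91 and 1.76). They were 0.81, 1.22 and -0.21 for Vegfa (0.45, 0.46 and 0.45), -0.42, -0.25 and -0.34 for Col1a1 (0.78 each), and 0.61, 0.99 and 0.36 for Krt6a (0.42, 0.42 and 0.41). Several turned on 1 library. Without post-MCS-01 replicate 2, Nos2 and Cxcl2 in post-MCS-01 were at -0.70 and -0.28 and Il1b at 0.43, and without pre-MCS-01 replicate 3 Nos2 in pre-MCS-01 was at -0.09. In DSCG, Arg1 and Cxcl2 were at -0.52 and -3.30 without DSCG replicate 1, Krt6a at -0.23 without DSCG replicate 2, and Il1b at 2.21 without blank replicate 1.

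Across all 4 groups at once, no gene passed (edgeR, smallest adjusted p = 0.166, 1369 genes at an unadjusted p under 0.05). The 10 smallest p belonged to Gzmb, Lyg2, Cldn17, Il20, Fam26d, Spdef, Chil3, Krt82, Slc26a4 and Krtap11-1. DESeq2 gave 553 genes, limma-voom 1, library quality weights 2189 and the newer edgeR fit 2, and the edgeR count was 273 without DSCG replicate 1. An exact permutation of the 12 libraries' list means (15400 splits, added after the data were seen) gave its smallest p for the M2 list (p = 0.00403, adjusted p = 0.111), and no list passed. The 54 other splits of the libraries of the 6 pairs of groups gave 6 to 22 lists past the preset threshold (median 15), against 12 to 22 for the treatment groups (median 18), so list calls with the preset correlation do not by themselves set treatment apart from other differences between mice.

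The 3 treatments were also compared for a shared response across genes. Because they share the blank libraries, Pearson correlations of their differences from blank near 0.58 arose in 100 simulated draws with no effect. The draws treated genes as independent and held no trend shared by libraries, such as that of transcript length. Their range therefore leaves out a structure that the real libraries hold, and a value outside it is not evidence of a treatment effect. The observed value was 0.631 for pre-MCS-01 and DSCG (simulated mean 0.581, highest 0.610), 0.250 for pre-MCS-01 and post-MCS-01 (0.580, 0.604) and 0.141 for post-MCS-01 and DSCG (0.582, 0.601). The covariance minus its simulated mean was -0.00852, -0.0158 and -0.0951. For pre-MCS-01 and DSCG the correlation lay above the highest draw and the covariance below the simulated mean, so whether these treatments shared a response beyond the common control stays open. For the other pairs both measures lay below the simulated means. These are values across genes, which are not independent replicates.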

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

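Of the tests in this part, those on a resting hair cycle, on library depth and transcript length, on single libraries and on other splits of the samples, and the fits with exon length as a covariate or without 3 libraries, were chosen only after the result was seen.

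Post-MCS-01 differed from pre-MCS-01 in 134 genes and from DSCG in 172 genes (edgeR). These are the direct comparisons given above, in which blank cancels out. No gene passed for any treatment against blank, so the 2 counts do not show which group departed from the control. The first count was 0 without pre-MCS-01 replicate 2 or any 1 post-MCS-01 library and 48 without pre-MCS-01 replicate 3, and the second was 606 without DSCG replicate 1 and 0 without any other 1 of its 6 libraries. The 10 splits of 6 libraries are too few for a share under 0.05, and 1 of 10 splits gave as many genes in each of these comparisons, the real one, with 0 as the highest other count in both. For pre-MCS-01, post-MCS-01 and DSCG against blank and pre-MCS-01 against DSCG, all 10 of 10 splits reach the real count of 0 by construction, which says nothing about chance, and the highest other counts were 85, 0, 0 and 16. At an unadjusted p under 0.05 these comparisons had 1178, 1521, 167 and 384 genes, and DESeq2 gave 74, 396, 0 and 15.

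Low hair genes in post-MCS-01 wounds are the pattern a biologist would most want to follow. Fewer follicles in the tissue was tested by genes of the permanent follicle. Their median log2 fold change was -0.44 against DSCG (interquartile range 1.27, 8 of 13 genes negative), far above the hair list's median of -8.94. Against blank their median was -1.17, with 11 of 13 negative. Expression of these genes outside follicles would limit their fall and was not measured, so fewer follicles cannot be ruled out. Loss of long transcripts is argued against as the cause of the fold, since the hair median was -8.73 with exon length as a covariate (interquartile range 2.80) and -8.36 without the 3 short libraries. The calls ended in both fits, with 0 of 27 hair genes past the threshold against 24, although the fold moved by less than the spread of the members, and these fits have fewer libraries or 1 more fitted term. A phase of the hair cycle without growing shafts may account for it and stays open as a hypothesis. Against DSCG, 11 of 11 signalling and matrix genes of the growing follicle were lower (median -1.52), Fgf5, Dlx3 and Hoxc13 past the threshold. Hoxc13 is also in the hair list, so its fall is not separate support. Against blank the median of these 11 genes was -1.25 (10 negative), close to the -1.17 of the permanent follicle genes. There the lists do not tell a cycle phase from fewer follicles. Between pre-MCS-01 and post-MCS-01 the growing follicle genes had a median of 2.18 (11 of 11 positive, 1 past the threshold). The permanent follicle genes had a median of 0.38 there (9 of 13 positive). That comparison shares the post-MCS-01 libraries with the one against DSCG and is not independent of it. Cycle phase may also differ with age or wound stage, which the labels do not give.

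The second pattern is the transcript-length trend of 3 libraries in 3 groups. Low depth is argued against, since 1 of them (DSCG replicate 2) held 115.1% of the median total. The correlation of deviation with log exon length was -0.320 or lower in each of the 3 and -0.0561 or higher in the other 9, which describes the trend that set these libraries apart and is no evidence for a cause. Its origin was not tested and stays open. Among 100 joint splits, 100 reach the real count of 0 genes (edgeR; 1369 at an unadjusted p under 0.05, and 553 with DESeq2) by construction, which says nothing about chance, but the highest other count, 1260, came from a split that put these 3 libraries in 1 group, which points to a structure of the samples other than treatment.

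The third pattern is the higher inflammatory list in post-MCS-01 than in DSCG, a difference of mean log2 CPM of 2.38 (SE 0.922). DSCG replicate 3 alone is argued against, since the difference was 1.57 without it (SE 0.505), and post-MCS-01 replicate 2 alone likewise, with 2.01 (SE 0.843). Treatment and other differences between the mice, such as wound stage, stay open and were not tested.

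The number of lists past the preset test does not set the treatments apart from other splits. The 54 other splits gave 6 to 22 lists (median 15) against 12 to 22 for the real groups (median 18). With 10 splits a pair, too few for a share under 0.05, splits with at least the real count numbered 1 (pre-MCS-01 against blank, real 22, highest other 17), 7 (post-MCS-01 against blank, 16, 21), 9 (DSCG against blank, 12, 18), 1 (pre-MCS-01 against post-MCS-01, 22, 21), 2 (pre-MCS-01 against DSCG, 20, 20) and 6 (post-MCS-01 against DSCG, 16, 22).

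The share of reads that matched more than 1 place, which no comparison used, averaged 20.6% in pre-MCS-01 (SD 2.13) and 19.9% in post-MCS-01 (SD 3.07), above the highest blank library at 18.5% (blank mean 17.8%, SD 0.638). The groups overlapped, with pre-MCS-01 replicate 2 at 18.2% and post-MCS-01 replicate 3 at 17.5%, and the difference was not tested.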

How the results depend on the processing

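The newer edgeR fit, the fit without 3 libraries short of long transcripts and the fit with exon length as a covariate were chosen only after the data were seen. No named gene's log2 fold change reversed with a call under any alternative run. All 134 genes of pre-MCS-01 against post-MCS-01 remained called with DESeq2, and all 172 of post-MCS-01 against DSCG. Across the choices fixed beforehand, 1245 values of named genes kept their side of the threshold, 171 lost it and 175 gained it. For the fits without 1 library, this tally holds only the lowest and highest value of a gene and the first lost call or sign change. It is therefore not a rate over all fits. A further 12 values, all of the fixed genes against blank and none past the threshold, changed sign with a shift above the standard error of the main value. Among them were Nos2 (-0.70) and Cxcl2 (-0.28) in post-MCS-01 without post-MCS-01 replicate 2, and 2 more did so under choices made after the data were seen. Changes of sign with a smaller shift were counted among the 1245. RLE scaling kept 132 of the 134 and 164 of the 172 called genes, and total counts 127 and 168. Total-count scaling moved the median log2 fold change of all genes from 0.03 to -0.08 for pre-MCS-01 against post-MCS-01. No paired analysis was possible because all mouse numbers differ. Low depth in blank replicate 3 limits genes near 0.786 CPM there. The cause of the changes below was not tested.

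DESeq2 gave 74 genes for pre-MCS-01 against blank, 396 for post-MCS-01 against blank, 425 for pre-MCS-01 against post-MCS-01, 15 for pre-MCS-01 against DSCG, 613 for post-MCS-01 against DSCG and 553 for the joint test. Limma-voom gave 1 for pre-MCS-01 against post-MCS-01, 2 for post-MCS-01 against DSCG and 1 for the joint test. With library quality weights these were 3818, 0 and 2189, with 2485 for pre-MCS-01 and 827 for post-MCS-01 against blank. A fit of the 2 groups alone gave 2 and 255 against blank and 0 for post-MCS-01 against DSCG. Post-MCS-01 against blank gave 37 without a filter and 63 with the newer fit, which gave 2 for the joint test. Without the 3 short libraries both direct comparisons gave 0, and with the covariate 1 for pre-MCS-01 against post-MCS-01 and 0 for post-MCS-01 against DSCG.

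Leaving out 1 library gave 0 to 131 genes for pre-MCS-01 against post-MCS-01 (131 without pre-MCS-01 replicate 1, 48 without pre-MCS-01 replicate 3, 0 without any other), 0 to 606 for post-MCS-01 against DSCG and 0 to 273 for the joint test (606 and 273 without DSCG replicate 1, 0 without any other).

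With an estimated correlation the list counts were 2 for pre-MCS-01 against post-MCS-01 and 0 in the other 5 comparisons. Leaving out 1 library gave 7 to 17 lists for DSCG against blank (7 without DSCG replicate 3) and 12 to 20 for pre-MCS-01 against DSCG (12 without DSCG replicate 1). The correlation of edgeR fold changes of post-MCS-01 and DSCG, -0.0732, turned to 0.0785 with limma-voom, 0.0445 to 0.0709 without 1 blank library and 0.176 without the 3 short libraries. It went from 0.156 to 0.430 for pre-MCS-01 and post-MCS-01 without those 3, and from 0.659 to 0.608 to 0.778 for pre-MCS-01 and DSCG without 1 blank library (0.778 without blank replicate 1).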

Other observations

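The exact permutation of list means and the differences of list means in log2 CPM without single libraries were chosen only after the data were seen.

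Ribosomal protein genes were higher in pre-MCS-01 than in post-MCS-01 in 23 of 23 members (mean log2 fold change 0.49, adjusted p = 0.000646, and adjusted p = 0.629 with an estimated correlation), a call that ended without pre-MCS-01 replicate 2 (adjusted p = 0.317), 1 of the 3 libraries short of long transcripts. In mean log2 CPM its difference of 0.42 was 0.12 without that library and 0.67 without pre-MCS-01 replicate 3. Collagen and matrix genes were lower in pre-MCS-01 than in blank in 22 of 23 members (mean -0.57, adjusted p = 1.84e-05, 0 over all genes and 1 adjusted over the list alone, Eln), with adjusted p = 0.505 with an estimated correlation and 0.184 without blank replicate 1. In mean log2 CPM that difference, -0.66, ranged from -1.26 to -0.22 without single libraries: -0.39, -0.32 and -1.26 without pre-MCS-01 replicates 1, 2 and 3, and -0.22 and -1.15 without blank replicates 1 and 3. The B and plasma cell list lay at a mean of -0.71 in pre-MCS-01 against blank (adjusted p = 0.00921, and adjusted p = 0.415 with an estimated correlation), and its call ended without pre-MCS-01 replicate 3 (0.0684) or blank replicate 3 (0.181), with a difference in mean log2 CPM of -0.70 that was -1.11 and -0.39 without blank replicates 1 and 3.

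The interferon response list lay at a mean of -0.02 in post-MCS-01 against blank (adjusted p = 0.761), the immediate early and heat shock list at -0.08 (0.868), the basal keratinocyte list at 0.16 (0.147) and the epidermal differentiation list at -0.20 (0.445). The neuropeptide list (mean -0.48, adjusted p = 0.445) held 1 gene lower when adjusted over the list alone, the corticotropin-releasing hormone receptor Crhr1 (-4.11 ± 1.12, adjusted p = 0.197 over all genes). The blood list (mean -0.88, adjusted p = 0.147) likewise held Slc4a1 (-4.69 ± 0.93, adjusted p = 0.0787 over all genes).

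In the exact permutation of list means over all 12 libraries, the melanocyte and oxidative stress lists had p = 0.0108 (adjusted p = 0.111), the hair list 0.0159 (adjusted p = 0.123), the inflammatory list 0.0351 and the adipocyte list 0.0380 (adjusted p = 0.196), and the mast cell list 0.660 (adjusted p = 0.771). Xist had 0 to 22 counts per library, and the Y-linked genes were counted in all 12 libraries, as in male mice.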
